A study of Homo sapiens with 18 samples.

How the data were processed

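RNA sequencing counts were analysed from 18 libraries of human H9 cells, an established embryonic stem cell line, and of cultures derived from it. The labels place 2 libraries in each of 9 groups. These are undifferentiated H9 cells, and, at day 4 (an endoderm stage in the labels) and day 12 (a hepatoblast stage), a control and cultures exposed to TBBPA, TBBPS or TCBPA. Doses, vehicle, culture batches and whether the replicates were separate cultures are not given in the sources used here.

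Per the labels' protocols, RNA was extracted with TRIzol and libraries were made at BGI. The submitters' processing notes name Trimmomatic, Bowtie2 (version 2.3.4.1-1), RSEM (version 1.2.28) and the human build hg38. They do not state a gene annotation. The authors deposited 1 table of RSEM expected counts per Entrez gene, the unit used throughout. An expected count divides a read that maps to several genes among them by estimated abundance, so between 42.5 and 43.6% of the values in a library, as given, had any decimal part other than 0 before rounding here. Genes that share sequence can therefore exchange reads, and read-through genes share reads with the genes they span. Such genes are reported as uncertain.

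The table held 19815 genes, of which 806 had no count in any library. Entrez identifiers were matched to symbols and to coordinates through a RefSeq gene table of the build GRCh38.p14, and 19624 matched. The 191 unmatched identifiers held 0.061% of counts. The 13 protein genes of the mitochondrial genome were not in the table, so the list made for them held 0 genes and was not analysed. The gene deposited under the older name TDGF1 is carried as CRIPTO.

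Totals ran from 17524503 to 18127040 expected counts per library, so depth differed little between groups. The 10 most counted genes held between 4.76 and 6.3% of a library. Pearson's r between the log2 CPM of replicates, across genes, lay between 0.9857 for TBBPS at day 12 and 0.9932 for H9. The chi-square of replicate differences per degree of freedom ran from 2.23 for TBBPA to 24.74 for TBBPS, both at day 12, and was 14.92 for TCBPA at day 12. Counting error alone gives a value near 1. At these depths a gene at 1 CPM holds about 18 counts per library, and genes below that are limited by counting error. Intervals computed from counts cover counting error only.

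Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on rounded counts. Genes with too few counts were removed by filterByExpr with a minimum count of 10, which left 16141 genes. Normalization used TMM factors, which lay between 0.97 and 1.035. One quasi-likelihood model held a mean for each of the 9 groups and left 9 residual degrees of freedom, with a prior of 5.36 and a common dispersion of 0.0076. F-tests were adjusted by the Benjamini-Hochberg method over all genes in a comparison, and an adjusted p under 0.05 counted as passed. Log2 fold changes are given with their standard error (SE), and intervals are at 95%. Where a group held 0 counts of a gene, the fold is a lower bound from a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its exact counting interval.

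The comparisons were the differentiation steps in untreated cultures, each compound against the control of its day, the mean of the 3 compounds against that control, each pair of compounds at each day, and, for each compound, the difference between its effects at days 12 and 4. In all, 47 gene lists with at least 3 tested genes were tested with camera from limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation. The lists covered developmental stages, hepatic functions, lipid metabolism, growth factor pathways, cell cycle, stress responses, and markers of other cell types that such cultures could hold. Adjusted p-values of lists are over the 47 lists of a comparison. Unless an estimated correlation is named, they come from the preset one. The fry test was also run, which asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. Counts of list members that passed are given over all genes and, where stated, adjusted over the list alone.

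Genes were named by a fixed rule. FGF10, FGFR2, MKI67, POU5F1, NANOG, SOX17, FOXA2, AFP, ALB and HNF4A could be named whatever their result. For each comparison with a control, the 5 genes with the largest passed changes in each direction could be added, and 3 in each direction for pairs, means and differences between days. These needed a mean of at least 1 CPM in a group compared and, between 2 groups, no overlap of libraries. Up to 4 members of each list with the smallest adjusted p completed the set, and XIST and Y-linked genes were left out. Some genes that passed are not reported here. The groups, tests, lists, alternatives and this rule were fixed before the data were examined, except for 5 alternatives that are said to have been added after seeing the data and the tests of explanations for single patterns, which were set out later.

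Alternatives were median-ratio size factors, a DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, a fit of the libraries of the days compared alone, and the removal of each library in turn. With 1 library removed, the lone library left in its group was assumed to vary like the other groups. The 5 additions were the difference between days of the mean of the compounds, list tests of those differences, list tests of pairs of compounds, a correction for GC content and transcript length, and a fit without genes that share over 0.5 of their 31-base words with other genes. Comparisons with the same control libraries were set beside 50 simulations with no effect.

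The steps were tested on simulated data drawn from the group means and library sizes, over 16064 genes. The TCBPA group at day 12 was given the control means of that day, apart from the genes changed on purpose. Of the genes changed 1.5-fold, 53.7% of 67 were recovered, of those changed 2-fold 80.6% of 67, and of those changed 4-fold 93.9% of 66. Among the unchanged genes 25 passed, beside 36, 54 and 62 of the genes changed 1.5-fold, 2-fold and 4-fold. False calls were thus a larger share of all calls in this simulation than the threshold on adjusted p aims for. A list seeded with changes had an adjusted p of 5.52e-97, and 1 of the other 47 lists passed. Genes were drawn independently of each other, so this does not test the preset correlation of the list test.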

Results

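Gene expression was measured by RNA sequencing in H9 human embryonic stem cells and in cultures differentiated from them towards liver, sampled at day 4 and day 12. At each of these days a control was set beside cultures exposed to tetrabromobisphenol A (TBBPA), tetrabromobisphenol S (TBBPS) or tetrachlorobisphenol A (TCBPA), which are halogenated bisphenols used as flame retardants. Each of the 9 groups held 2 libraries. Expected counts per library totalled 18127040 and 18120843 in H9. The day 4 libraries held between 17531711 (control replicate 2) and 18109316 (TBBPS replicate 1), and the day 12 libraries between 17524503 (TBBPA replicate 2) and 18059993 (control replicate 2). The series asks whether the compounds disturb hepatic differentiation and raise proliferation, and names the growth factor FGF10 as a possible route. All p-values below measure only the spread between these libraries, since the labels do not say that replicates were separate cultures.

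The stage of the cultures separated the libraries most. The first principal component of log2 CPM held 78.4% of the variance and parted day 12, from 92.7 to 114.2, from day 4 and H9. The second held 12.6% and parted H9 from the rest. Within day 12 alone, the first component held 39.2% of the variance. There the controls lay at -26.1 and -29.8 and the TCBPA libraries at 32 and 6.3, with TBBPA at 3.8 and 3.7. TBBPS was split, with replicate 1 at 27.5 and replicate 2 at -17.2.

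**Figure D1:**
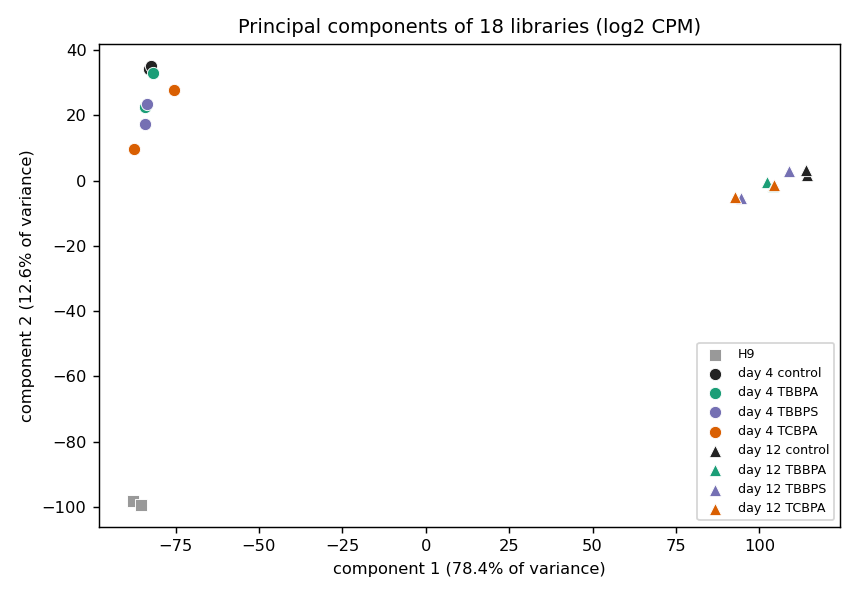
Scores of the 18 libraries on the first and second principal components of log2 CPM, with the percent of variance on each axis. Each point is 1 library, squares are H9, circles day 4 and triangles day 12, and colour gives the treatment. The treated day 12 libraries lie between 92.7 and 108.9 on the first component, below the controls at 114.2 and 114.1.

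The day 4 control was compared with H9 to describe the first step of differentiation without compound. Endoderm genes went from near absence to high expression. Of the 17 definitive endoderm genes, 16 rose and 1 fell, with a median log2 fold change of 5.85 (adjusted p = 2.44e-19; adjusted p = 0.116 with an estimated correlation). SOX17, a transcription factor of endoderm, had 0 counts in H9 and was at least 3040-fold higher at day 4, and GATA6, another, was at least 4100-fold higher. CXCR4, a chemokine receptor used to sort endoderm, rose by 8.78 ± 0.54 on the log2 scale (SE, n = 2 per group, adjusted p = 6.92e-10). FOXA2 had 3353 counts at day 4 against 2 in H9, a ratio of 1740 with a counting interval of 482 to 14400.

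Genes of the primitive streak, the embryonic source of endoderm, were also higher at day 4. Of 11 tested, 7 rose and 1 fell (median 4.69, or 3.77 with genes absent from H9 at their bound; adjusted p = 1.3e-13, and adjusted p = 0.0545 with an estimated correlation). They included MIXL1 (5.73 ± 0.28) and NODAL (3.77 ± 0.20), a signalling ligand that induces endoderm. Of 15 hepatoblast genes 9 rose and 2 fell (adjusted p = 0.00485; adjusted p = 0.666 with an estimated correlation), among them HNF4A, a regulator of liver genes (7.67 ± 1.02). Wnt and TGF-beta target lists passed as well, each with no member lower. SP5 and AXIN2, which report Wnt signalling, rose by 6.93 ± 0.66 and 1.44 ± 0.16. CCN2 and PMEPA1, targets of TGF-beta, rose by 2.34 ± 0.22 and 1.62 ± 0.10. In total 5 of 10 Wnt targets rose (adjusted p = 0.00221; adjusted p = 0.116 with an estimated correlation) and 7 of 11 TGF-beta targets rose (adjusted p = 0.00143; adjusted p = 0.197 with an estimated correlation). Of the 12 immediate early genes, which respond within minutes to growth factors, 7 rose and 1 fell (adjusted p = 0.00291; adjusted p = 0.595 with an estimated correlation), led by JUN (3.79 ± 0.18).

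Lipid synthesis was lower at day 4. Of 21 genes of cholesterol synthesis, 20 fell and none rose, with a median of -0.88 (adjusted p = 2.58e-07; adjusted p = 0.694 with an estimated correlation). FDFT1, squalene synthase, changed by -1.47 ± 0.10 and INSIG1, a sterol sensor, by -1.96 ± 0.17. Of 9 genes of fatty acid synthesis 7 fell and 1 rose (adjusted p = 9.8e-05; adjusted p = 0.197 with an estimated correlation), including ACACA (-1.20 ± 0.07). Pluripotency genes were mixed: 11 of 18 fell and 2 rose, and the list did not pass (adjusted p = 0.0633). POU5F1 fell from 1920 ± 18 to 1120 CPM (-0.78 ± 0.22, adjusted p = 0.0086), whereas NANOG did not pass (-0.15 ± 0.15, adjusted p = 0.409).

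FGF genes moved in different directions at this step. FGF8 rose by 4.69 ± 0.31 and FGF19 changed by -3.87 ± 0.29. FGF10, an FGF ligand that signals mainly through FGFR2, had 32 counts in the day 4 controls and 3 in H9, a ratio of 11.1 with a counting interval of 3.47 to 56.6. In total 8726 genes passed in this comparison, 4530 higher and 4196 lower, and 2864 of them changed at least 2-fold. Of the 47 gene lists, 10 passed and none did with an estimated correlation, while fry passed 26. The 10 MTRNR2L genes, nuclear copies related to mitochondrial 16S ribosomal RNA, together held 0.826 and 0.845% of the H9 counts and at most 0.000382% in the other 16 libraries. The most counted gene was LRRK1 in both H9 libraries (1.68 and 1.59% of counts) and EEF1A1 in the other 16. A difference in how the H9 libraries were prepared or mapped cannot be told apart from cell stage in this comparison.

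From day 4 to day 12 the control cultures gained hepatic transcripts. Of 16 secreted hepatocyte proteins 15 rose and none fell, with a median of 8.72, or 8.65 with genes absent at day 4 at their bound (adjusted p = 6.11e-07; adjusted p = 0.34 with an estimated correlation). AFP, the fetal plasma protein that marks hepatoblasts (Entrez 174, chromosome 4, 73436221 to 73456174, GRCh38.p14), went from 0.259 ± 0.04 to 1130.0 ± 31 CPM (SD, n = 2). APOA1 and APOB, which carry lipids in plasma, rose by 7.98 ± 0.37 and 9.08 ± 0.65, and FGB, a fibrinogen chain, was at least 28000-fold higher. ALB rose by 3.63 ± 0.82 (adjusted p = 0.000151) but stayed at 1.86 ± 0.27 CPM. HNF4A (Entrez 3172, chromosome 20, 44355699 to 44434596) rose from 58.0 ± 1.2 to 188 ± 1.2 CPM, and CEBPA, a transcription factor of hepatocytes, by 5.26 ± 0.28.

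Hepatoblast genes (11 of 15 higher, 2 lower; adjusted p = 0.00459, and adjusted p = 0.357 with an estimated correlation) and cholesterol synthesis (17 of 21 higher, 1 lower; adjusted p = 0.00324, and adjusted p = 0.609 with an estimated correlation) also rose between these days. Drug metabolism genes rose in 11 of 16 and fell in 1 (adjusted p = 0.0321; adjusted p = 0.145 with an estimated correlation), among them GSTA1, a glutathione transferase (8.30 ± 0.99), and ABCC2, a bile pigment exporter (3.50 ± 0.44). Bile duct genes were also higher (6 of 9, 1 lower; adjusted p = 0.00038, and adjusted p = 0.109 with an estimated correlation), with SOX9 at 4.43 ± 0.16 and KRT19 at 3.27 ± 0.18. All 9 tested HOX genes rose, most of them from 0 counts (median with bounds 5.83; adjusted p = 1.42e-05, and adjusted p = 0.145 with an estimated correlation).

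A pair of lists of other fates or pathways passed upward with an estimated correlation too, each at adjusted p = 0.00171. Of 10 BMP targets 9 rose and none fell, with ID2 at 5.37 ± 0.13 and MSX2 at 6.64 ± 0.22 (median 3.55). Of 11 genes of surface ectoderm and trophoblast, 10 rose and none fell, among them KRT7 (8.29 ± 0.31) and TFAP2C (3.12 ± 0.15). The FGF and ERK response list passed downward under the same test, again at adjusted p = 0.00171, with 13 of 14 genes lower and none higher (median -3.85). ETV4, SPRY4 and DUSP4, which ERK signalling induces, changed by -4.93 ± 0.16, -8.33 ± 0.38 and -4.91 ± 0.18.

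Early programmes and the cell cycle receded over the same interval. Pluripotency genes fell in 17 of 18 (median -3.43; adjusted p = 9.66e-17, and adjusted p = 0.0506 with an estimated correlation), with POU5F1 at 54.4 CPM and NANOG changed by -4.82 ± 0.22. All 20 genes of G2 and M phase fell (median -2.02; adjusted p = 5.56e-18, and adjusted p = 0.145 with an estimated correlation), and 19 of 20 genes of S phase fell while 1 rose (median -1.26; adjusted p = 0.000388, and adjusted p = 0.538 with an estimated correlation). MKI67, a marker of dividing cells (Entrez 4288, chromosome 10, 128096659 to 128126423), changed by -2.54 ± 0.11 (adjusted p = 1.12e-10). FGF10 (Entrez 2255, chromosome 5, 44300247 to 44389420) fell from 0.922 ± 0.25 to 0.278 ± 0.078 CPM, a change of -1.70 ± 0.43 (adjusted p = 0.00148). Of 19 FGF ligands 12 fell and 1 rose, while 5 of 6 FGF receptors and co-receptors rose, including KLB (5.19 ± 0.35) and FGFR4 (2.35 ± 0.21). Those lists had adjusted p = 0.145 and adjusted p = 0.343 with an estimated correlation. In this step 11658 genes passed, 5827 higher and 5831 lower, and 23 lists passed, against 41 with fry.

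Each compound was compared with the control at day 4, to see whether it altered the endoderm stage. Few single genes passed. PRRG3, a vitamin K-dependent membrane protein (Entrez 79057, chromosome X, 151694607 to 151705924), fell with TCBPA from 65.5 ± 0.18 to 32 ± 2.3 CPM (-1.03 ± 0.14, adjusted p = 0.048). It was the only gene to pass for TCBPA in edgeR, where 2172 genes had an unadjusted p under 0.05 and DESeq2 called 111. For TBBPA edgeR passed 0 genes, with 780 at an unadjusted p under 0.05 and 2 by DESeq2, and for TBBPS 0, with 2278 and 115. About 807 genes would reach that unadjusted level by chance. For TCBPA the count was 0 without control replicate 1 or without TCBPA replicate 1, 28 without control replicate 2 and 491 without TCBPA replicate 2. For TBBPA it was 11, and for TBBPS 3, without control replicate 2.

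Over the mean of the 3 compounds at day 4, PRRG3 (-0.89 ± 0.11, adjusted p = 0.0138) and the read-through gene MSANTD3-TMEFF1 (-0.61 ± 0.09, adjusted p = 0.0474) were lower. In all 3 genes passed in edgeR against 161 in DESeq2. MSANTD3-TMEFF1 shares reads with its component genes and is uncertain. The count of genes was 0 without control replicate 1, TBBPA replicate 1 or TBBPS replicate 2, 1 without TCBPA replicate 1, 31 without control replicate 2 and 401 without TCBPA replicate 2.

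At day 4 no gene list passed with an estimated correlation. For each compound and for their mean fry passed 0 lists. Over the mean of the compounds the 12 immediate early genes all had negative fold changes (median -0.44, adjusted p = 1.42e-05; adjusted p = 0.316 with an estimated correlation), and 6 fell when adjusted over the list alone. For TCBPA 5 of them fell, adjusted over the list alone, including ATF3 (-0.69 ± 0.15, adjusted p = 0.144 over all genes). Of 15 p53 targets, 4 rose for the mean when adjusted over the list alone (median 0.21, adjusted p = 9.71e-05; adjusted p = 0.316 with an estimated correlation). TGF-beta targets had a median of -0.21 (adjusted p = 0.000796; adjusted p = 0.316 with an estimated correlation). These 3 lists rested on control replicate 1: without it their adjusted p-values were 0.169, 0.284 and 0.225.

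Endoderm genes leaned lower with TBBPS and TCBPA at day 4, and pluripotency genes leaned higher. The endoderm list had a median of -0.44 for the mean of the compounds (adjusted p = 0.000323; adjusted p = 0.693 with an estimated correlation), which lost the call without control replicate 2 (adjusted p = 0.0543). With TCBPA the median was -0.57 (adjusted p = 5.57e-05; adjusted p = 0.619 with an estimated correlation) and with TBBPS -0.58 (adjusted p = 0.000306; adjusted p = 0.702 with an estimated correlation), and 0 of the 17 genes passed over all genes for either. With TBBPA the median was -0.2 and the list did not pass (adjusted p = 0.347). CXCR4 stood at -0.71 ± 0.22 with TCBPA and -0.65 ± 0.22 with TBBPS (adjusted p = 0.237 for both). Replicates differed, with mean scores of -0.86 and -0.14 in the TCBPA libraries, and without TCBPA replicate 1 the TCBPA list did not pass (-0.18, adjusted p = 0.102). Pluripotency genes had a median of 0.18 for the mean (adjusted p = 0.000493; adjusted p = 0.693 with an estimated correlation), with 4 of 18 higher when adjusted over the list alone.

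TCBPA replicate 2 of day 4 held transcripts of day 12. Its secreted hepatocyte proteins scored 2.07 above the day 4 controls, and 16 genes that are near absent from the other day 4 libraries were present at about 0.769% of their day 12 level. Single genes ranged from 0.306% for TFAP2A to 1.38% for SERPINA1. The other day 4 libraries lay between -0.0212 and 0.0128%, but the genes were chosen for being low there. The secreted protein list passed upward for TCBPA at day 4 (median 0.87, adjusted p = 0.000929; adjusted p = 0.621 with an estimated correlation) and stood at -0.07 without that library (adjusted p = 0.848). The list of surface ectoderm and trophoblast (median 0.93, adjusted p = 0.0002; adjusted p = 0.0804 with an estimated correlation) had a median of 0.83 without it (adjusted p = 0.139). Its score was 0.54 in TCBPA replicate 1 and from 0.3 to 0.41 in the TBBPA and TBBPS libraries, so that rise is not confined to replicate 2.

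At day 12 TCBPA was compared with the control to see whether it altered the hepatoblast stage. Cell cycle genes were higher and hepatic genes lower. All 20 genes of G2 and M phase rose, by a median of 0.65 (adjusted p = 8.48e-29; adjusted p = 0.231 with an estimated correlation), and 18 of 20 genes of S phase, by 0.81 (adjusted p = 3.05e-20; adjusted p = 0.231 with an estimated correlation). MKI67 rose from 55.2 ± 1.5 to 91.7 ± 4.4 CPM (0.73 ± 0.11, adjusted p = 0.00614). ANLN, TPX2 and AURKB, which act in mitosis, rose by 0.63 ± 0.08, 0.65 ± 0.09 and 0.76 ± 0.11, and CDC6, which licenses replication origins, by 1.04 ± 0.18. CDKN1C, an inhibitor of the cell cycle, fell by 1.32 on the log2 scale (SE 0.27, adjusted p = 0.0135).

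Among the hepatic genes, 11 of 16 secreted proteins fell with TCBPA and none rose, with a median of -1.37 (adjusted p = 1.03e-07; adjusted p = 0.291 with an estimated correlation). When adjusted over the list alone 13 fell. AHSG, VTN and RBP4, plasma proteins made by the liver, changed by -2.08 ± 0.35, -1.42 ± 0.22 and -1.62 ± 0.35. AFP went from 1130.0 ± 31 to 264 ± 150 CPM (-2.09 ± 0.49, adjusted p = 0.0224), and DESeq2 did not call it (adjusted p = 0.0862). ALB, at under 2 CPM, did not pass (-0.44 ± 0.44, adjusted p = 0.594). HNF4A fell from 188 ± 1.2 to 101 ± 16 CPM (-0.89 ± 0.24, adjusted p = 0.0343) and FOXA2 by 1.15 on the log2 scale (SE 0.32, adjusted p = 0.0433). Coagulation and complement genes fell in 5 of 12 (median -0.95, adjusted p = 1.46e-05; adjusted p = 0.239 with an estimated correlation), including PLG, plasminogen (-1.79 ± 0.34). Definitive endoderm genes that remain in use in liver, such as GATA4 (-1.19 ± 0.30), were among 5 of 17 that fell (adjusted p = 0.000187; adjusted p = 0.363 with an estimated correlation).

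Cholesterol synthesis fell with TCBPA at day 12 in 15 of 21 genes, and in 20 adjusted over the list alone, by a median of -0.62 (adjusted p = 5.47e-19; adjusted p = 0.231 with an estimated correlation). MSMO1 and HMGCS1, enzymes of the pathway, changed by -0.87 ± 0.14 and -0.83 ± 0.16. Of 9 genes of fatty acid synthesis, 2 fell, FADS2 (-0.48 ± 0.12) and ACLY (-0.33 ± 0.09; list adjusted p = 0.0142, and adjusted p = 0.291 with an estimated correlation). Hypoxia and glycolysis genes fell in 4 of 13, among them ADM (-0.81 ± 0.18; list adjusted p = 0.0133, and adjusted p = 0.291 with an estimated correlation). NRF2 targets fell in 4 of 10, with NQO1, a quinone reductase, at -1.15 ± 0.19 (list adjusted p = 0.0133, and adjusted p = 0.291 with an estimated correlation), but the list did not pass without TCBPA replicate 1 (adjusted p = 0.066).

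FGF pathway genes changed with TCBPA in both directions at day 12. FGF10 rose from 0.278 ± 0.078 to 1.04 ± 0.15 CPM, a log2 fold change of 1.88 ± 0.42 (95% interval 0.98 to 2.78, adjusted p = 0.0137). This rests on 4 and 6 counts in the controls and 17 and 21 with TCBPA, and DESeq2 gave it no adjusted p. FGFR2 did not pass (-0.22 ± 0.10, adjusted p = 0.184). Of 6 FGF receptors and co-receptors 3 fell, FGFRL1 (-0.86 ± 0.17), FGFR4 (-1.03 ± 0.20) and KLB (-1.03 ± 0.21), and the list passed (adjusted p = 0.000187; adjusted p = 0.239 with an estimated correlation). DUSP6 (1.58 ± 0.32), ETV5 (1.76 ± 0.52) and SPRY2 (0.47 ± 0.13), targets of ERK signalling, were the 3 of 14 response genes that rose (list adjusted p = 1.44e-05; adjusted p = 0.231 with an estimated correlation).

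The largest passed changes with TCBPA at day 12 included LPL, a lipase of triglyceride uptake, which rose from 0.139 ± 0.04 to 2.44 ± 0.65 CPM (4.07 ± 1.30, adjusted p = 0.0188). NXPH2 and IRX1 also rose, by 2.56 ± 0.70 and 2.25 ± 0.58. The nuclear receptor NR2F1 (-2.76 ± 0.59), the kinin precursor KNG1 (-2.50 ± 0.64) and the apolipoprotein APOA5 (-2.37 ± 0.65) were among the lowest. DESeq2 gave no adjusted p for NXPH2, NR2F1, KNG1 and APOA5. TMED7-TICAM2 (-2.83 ± 0.93) is a read-through gene and is uncertain. In all 1312 genes passed, 497 higher and 815 lower, and 281 changed at least 2-fold, 40 higher and 241 lower. DESeq2 called 1494. Of the lists 18 passed, 7 higher and 11 lower, none with an estimated correlation, and fry passed 15.

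These single-gene calls depended on the libraries in the fit. The model pooled the spread of all 9 groups, but replicates of TCBPA at day 12 differed more than those of the control (chi-square per degree of freedom 14.92 against 4.15). With the 8 libraries of day 12 alone no gene passed, and the adjusted p was 0.104 for FGF10, 0.102 for MKI67, 0.118 for AFP and 0.11 for HNF4A, while their fold changes were the same to 2 decimals. The count was 0 without control replicate 2, so that none of the single-gene calls above was kept, 199 without control replicate 1, 19 without TCBPA replicate 1 and 1637 without TCBPA replicate 2. FGF10 did not pass without control replicate 1 (adjusted p = 0.0926), control replicate 2 (0.0827) or TCBPA replicate 1 (0.0829), where it stood at 1.62, 2.18 and 2.01. AFP and HNF4A likewise did not pass without any 1 of these 3 libraries, with adjusted p from 0.0796 to 0.21 and from 0.124 to 0.267. MKI67 did not pass without control replicate 2 (adjusted p = 0.0642) or TCBPA replicate 1 (0.0665). The lists of G2 and M phase, S phase, secreted proteins and cholesterol synthesis passed without each library in turn.

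TBBPA and TBBPS were compared with the same day 12 controls. Fold changes of FGF10, MKI67, AFP and HNF4A had the signs seen with TCBPA, but single genes did not pass, apart from PRC1, a protein of the mitotic spindle (Entrez 9055, chromosome 15, 90966040 to 90994535). It rose with TBBPS from 28.9 ± 1.4 to 43.4 ± 4 CPM (0.59 ± 0.08, adjusted p = 0.0498) but did not pass without control replicate 1 (adjusted p = 0.0772), control replicate 2 (0.451) or TBBPS replicate 1 (0.276). FGF10 stood at 1.85 ± 0.42 with TBBPA (adjusted p = 0.188) and 1.60 ± 0.43 with TBBPS (adjusted p = 0.129), with no adjusted p from DESeq2 for either. MKI67 stood at 0.45 ± 0.11 and 0.54 ± 0.11 (adjusted p = 0.188 and 0.102), and DESeq2 called it for both (adjusted p = 0.0238 and 0.00206). AFP stood at -1.34 ± 0.48 and -1.25 ± 0.48 (adjusted p = 0.264 and 0.245).

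At the level of lists, G2 and M phase genes were higher with TBBPA (median 0.42, adjusted p = 5.77e-23; adjusted p = 0.189 with an estimated correlation) and with TBBPS (0.53, adjusted p = 4.03e-28; adjusted p = 0.284 with an estimated correlation). Adjusted over the list alone, 19 and 20 of the 20 genes rose. S phase genes had medians of 0.54 and 0.65 (adjusted p = 0.189 and adjusted p = 0.336 with an estimated correlation), and 18 and 19 of 20 rose, adjusted over the list alone. Secreted hepatocyte proteins had medians of -0.83 with TBBPA (adjusted p = 7.01e-06; adjusted p = 0.35 with an estimated correlation) and -0.82 with TBBPS (adjusted p = 2.85e-06; adjusted p = 0.348 with an estimated correlation), and 7 and 4 of 16 fell, adjusted over the list alone. Cholesterol synthesis had medians of -0.36 and -0.34 (adjusted p = 3.24e-13 and 1.7e-12; adjusted p = 0.216 and adjusted p = 0.348 with an estimated correlation), and 9 and 7 of 21 genes fell, adjusted over the list alone. The interferon response list was lower with TBBPA (median -0.24, adjusted p = 0.015; adjusted p = 0.189 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.102). It did not pass for TBBPS (adjusted p = 0.0741) or TCBPA (adjusted p = 0.243), nor did its difference between TBBPA and either of them (adjusted p = 0.626 and 0.378). Of the 47 lists 16 passed for TBBPA and 13 for TBBPS, and fry passed 0 for both.

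The replicates of TBBPS at day 12 lay apart in these same lists. Relative to the controls, secreted proteins scored -1.51 in replicate 1 and -0.34 in replicate 2, cholesterol synthesis -0.68 and -0.11, and G2 and M phase 0.71 and 0.29. For TBBPS edgeR passed 1 gene, with 2541 at an unadjusted p under 0.05 and 254 by DESeq2. Without TBBPS replicate 2 it passed 2182, among them AFP (-2.53, adjusted p = 0.00196) and FGF10 (1.81, adjusted p = 0.0225). It passed 4 without control replicate 1, 0 without control replicate 2 and 2 without TBBPS replicate 1. For TBBPA it passed 0 genes, with 2226 at an unadjusted p under 0.05 and 107 by DESeq2, 6 without control replicate 1 and 1 without TBBPA replicate 2.

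**Figure D2:**
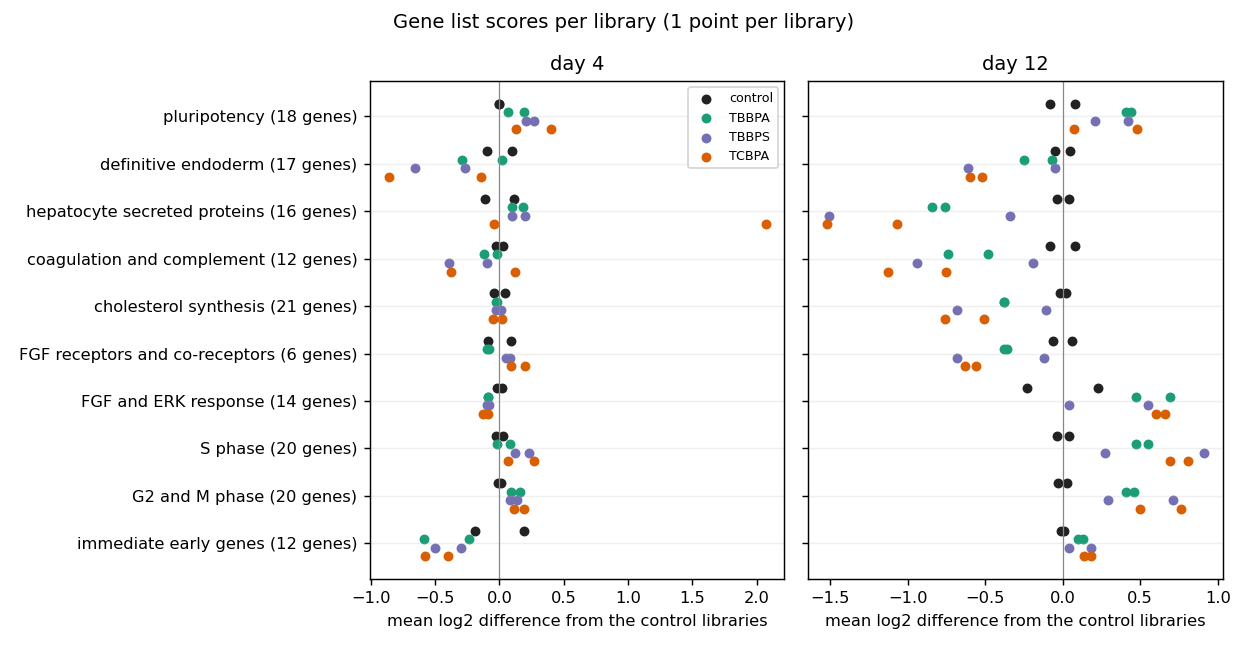
Mean log2 difference from the control libraries of the same day for 10 gene lists, with day 4 and day 12 in separate panels. Each point is 1 library and colour gives the treatment. At day 12 the G2 and M phase scores of TBBPS replicates 1 and 2 were 0.71 and 0.29, and their secreted hepatocyte protein scores -1.51 and -0.34. At day 4 TCBPA replicate 2 stands apart in secreted hepatocyte proteins at 2.07.

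The mean of the 3 compounds was tested against the day 12 control to describe their average change, which need not be shared by all 3. In edgeR 0 genes passed for TBBPA alone, 1 for TBBPS and 1312 for TCBPA. Cell cycle genes rose, with 20 of 20 in G2 and M phase (median 0.53, adjusted p = 3.86e-28; adjusted p = 0.22 with an estimated correlation) and 18 of 20 in S phase (median 0.66, adjusted p = 1.72e-19; adjusted p = 0.247 with an estimated correlation). Secreted hepatocyte proteins fell in 10 of 16 (median -1.01, adjusted p = 5.09e-08; adjusted p = 0.255 with an estimated correlation) and cholesterol synthesis in 13 of 21 (median -0.43, adjusted p = 3.88e-17; adjusted p = 0.247 with an estimated correlation). FGF10 rose by 1.78 ± 0.38 (adjusted p = 0.012) and MKI67 by 0.58 ± 0.09 (adjusted p = 0.00788). AFP changed by -1.56 ± 0.39 (adjusted p = 0.0221), HNF4A by -0.66 ± 0.19 (adjusted p = 0.0465), and MMP1, a collagenase, by -1.67 ± 0.42 (adjusted p = 0.0305). DESeq2 called neither AFP (adjusted p = 0.128) nor HNF4A (adjusted p = 0.0779), and it gave no adjusted p for FGF10 and MMP1. The count was 1234 genes, 475 higher and 759 lower, against 1448 in DESeq2, and fry passed 21 lists.

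No gene passed for this mean with the day 12 libraries alone. The count was also 0 without control replicate 2 and 39 without control replicate 1. It was 618 and 611 without TBBPA replicate 1 or 2, 759 without TCBPA replicate 1, 1930 without TCBPA replicate 2 and 2962 without TBBPS replicate 2. FGF10 did not pass without control replicate 1 (adjusted p = 0.115) or 2 (0.15), nor did MKI67 (0.0702 and 0.15), AFP (0.122 and 0.19), HNF4A (0.205 and 0.257) or MMP1 (0.134 and 0.257). AFP also missed without TBBPA replicate 1 (0.0552) or 2 (0.054), and HNF4A without those (0.0967 and 0.0859) or TCBPA replicate 1 (0.0868). MMP1 missed without TBBPA replicate 2 (0.0717) or TCBPA replicate 1 (0.0512).

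Fold changes with different compounds were correlated across genes, which are not independent replicates. At day 12 r was 0.83 for TBBPA and TBBPS, 0.87 for TBBPA and TCBPA and 0.84 for TBBPS and TCBPA. The shared controls alone gave 0.50 in simulations with no effect. The observed covariances of 0.0648, 0.0855 and 0.0881 stood beside a simulated 0.0199 and 0.016 estimated from the control replicates. At day 4 r was 0.68, 0.68 and 0.78 in the same order against 0.50 to 0.51, with covariances of 0.0365, 0.0381 and 0.0569 beside 0.0196 to 0.0197 simulated and 0.0216 from the control replicates. The control replicates were not divided between the compounds for these correlations, so part of the excess may come from the shared controls.

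The compounds were compared with each other at each day, with doses not in the labels. TBBPA and TBBPS carry bromine on different bisphenol cores, and TBBPA and TCBPA carry bromine or chlorine on the same core. At day 12 the FGF10 difference was 0.25 between TBBPA and TBBPS (95% interval -0.45 to 0.95), -0.03 between TBBPA and TCBPA (-0.70 to 0.65) and -0.28 between TBBPS and TCBPA (-0.97 to 0.42). The MKI67 differences were -0.09 (-0.33 to 0.15), -0.28 (-0.51 to -0.04) and -0.19 (-0.42 to 0.05). Those of AFP were -0.09 (-1.13 to 0.95), 0.76 (-0.28 to 1.80) and 0.85 (-0.20 to 1.89). None of these passed, with adjusted p = 1.0 for each, and the intervals reach 0.97 on the log2 scale in size for FGF10 and 1.89 for AFP. At day 4 the FGF10 differences were 0.34 (-0.31 to 1), 1.22 (0.48 to 1.96) and 0.88 (0.12 to 1.63) in the same order. Both intervals against TCBPA exclude 0 for this gene alone, but neither difference passed once adjusted over all genes.

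Some lists differed between TCBPA and TBBPA at day 12, in tests added after seeing the data, though fry passed 0 lists for any pair of compounds or difference between days. TBBPA exceeded TCBPA in secreted proteins by a median of 0.54 (adjusted p = 0.000233; adjusted p = 0.602 with an estimated correlation) and in cholesterol synthesis by 0.24 (adjusted p = 3.77e-10; adjusted p = 0.602 with an estimated correlation). It lay below TCBPA in S phase by -0.26 (adjusted p = 1.12e-08) and in G2 and M phase by -0.21 (adjusted p = 1.11e-11), each with adjusted p = 0.602 with an estimated correlation. Without TCBPA replicate 1, only the S phase list still passed, and the others had adjusted p = 0.12, 0.0821 and 0.11. The differences between TBBPS and the other compounds turned with the TBBPS library left out: S phase for TBBPA against TBBPS was -0.10 with both, 0.25 without replicate 1 and -0.43 without replicate 2.

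Single genes did not pass between compounds, except 1 at day 4. The read-through gene COMMD3-BMI1 was higher with TBBPS than with TCBPA (1.39 ± 0.19, adjusted p = 0.0342), but it shares 96% of its words with other genes and is uncertain. That call was lost without any 1 of the 4 libraries compared, with adjusted p from 0.0635 to 0.921. Among the other pairs edgeR passed 0 genes. At an unadjusted p under 0.05 there were 569, 529 and 377 at day 4 and 243, 501 and 654 at day 12, in the order TBBPA against TBBPS, TBBPA against TCBPA and TBBPS against TCBPA. Each of these counts lay below the 807 or so that would reach that level by chance. DESeq2 called 0, 0 and 2 at day 4, and 0, 1 and 0 at day 12. For TBBPS against TCBPA at day 12 the edgeR count was 534 without TBBPS replicate 1 and 2 without TCBPA replicate 1. It was 1 without TBBPA replicate 2 for each pair with TBBPA at that day.

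Whether a compound acted differently at the 2 days was tested as the difference between its effects. For TCBPA 5 genes passed. PRRG3 (1.5 ± 0.20, adjusted p = 0.0186), DIAPH3, an actin regulator of cell division (1.05 ± 0.15, adjusted p = 0.0254), and ANLN (0.76 ± 0.10, adjusted p = 0.0186) had a higher effect at day 12. TMEM158 (-2 ± 0.27, adjusted p = 0.0186) and GPRC5B (-1.24 ± 0.19, adjusted p = 0.0412) had a lower one. FGF10 stood at 0.569 ± 0.083 CPM with TCBPA and 0.922 ± 0.25 in controls at day 4 (-0.69 ± 0.36, adjusted p = 0.444), and its difference between days did not pass (2.57 ± 0.56, adjusted p = 0.0726). DESeq2 called 378 genes for this difference, and edgeR had 2589 at an unadjusted p under 0.05. The count was 100 without day 4 TCBPA replicate 2, 0 without day 4 control replicate 1 or day 12 control replicate 2, and 9, 8, 1 and 2 without day 4 control replicate 2, day 12 control replicate 1, and day 12 TCBPA replicates 1 and 2.

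For TBBPA and TBBPS edgeR passed 0 genes in the difference between days, with 1416 and 2125 at an unadjusted p under 0.05 and 0 and 68 by DESeq2. The TBBPA count was 1 without day 4 control replicate 2. The TBBPS count was 963 without day 12 TBBPS replicate 2 and 1 without day 12 control replicate 1. For the mean of the 3 compounds, a test added after seeing the data, 31 genes passed, 13 higher and 18 lower, against 424 in DESeq2. They included DEPP1 (-2.96 ± 0.64, adjusted p = 0.0416) and the metallothionein MT1G (-1.67 ± 0.25, adjusted p = 0.0328). FGF10 did not pass (1.77 ± 0.47, adjusted p = 0.0893) but did without day 12 TBBPS replicate 2 (1.83, adjusted p = 0.0267). The count was 0 without any 1 of 6 libraries, which were day 4 control replicate 1, TBBPA replicate 1 and both TBBPS replicates, and day 12 control replicate 2 and TBBPA replicate 1. It was 1340 without day 12 TBBPS replicate 2, 269 without replicate 1, 144 without day 12 TCBPA replicate 2 and 135 without day 4 TCBPA replicate 2.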

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

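Among the tests in this part, those of a smaller share of hepatic cells, a mislabelled library, words of the 16S ribosomal RNA and the wider carry-over were chosen only after the result they test was seen, and the others were set out before they were run.

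With TCBPA at day 12 the lists of G2 and M phase and S phase were higher and those of secreted hepatocyte proteins and cholesterol synthesis lower. Bias from GC content or transcript length was excluded as the source, since the 4 lists kept at least 97% of their median after correction for both. Scaling moved by a few abundant genes was not a likely source. The 50 most counted genes held 14 and 14.1% of the control counts at day 12, and 14.6 and 13.7% with TCBPA. At least 99.5% of the medians was kept with these genes out of the scaling. With shares so alike, leaving them out could hardly have changed the medians, so this test adds little. A smaller share of hepatic cells with an unchanged profile would lower all their abundant products alike, and the fold changes of 10 such proteins of the secreted list, chosen by their level and rise in controls, spanned 0.76, from -1.84 for TTR to -1.07 for APOA1 (chi-square 4 on 9 degrees of freedom, p = 0.914), not counting AFP of the hepatoblast list at -2.09. SEs of single genes were wide at day 12, 0.34 for APOA1 and 0.49 for TTR between TBBPA and TCBPA. The chi-square could therefore miss differences of this size, and it does not show that the changes were alike. A smaller hepatic share stays open and could hold together with slower differentiation or changed regulation within cells, which bulk counts do not separate.

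TCBPA replicate 2 of day 4 held day 12 transcripts, such as 239 counts of FGB. A day 12 library wholly mislabelled as day 4 was excluded, since the genes tested reached 0.707% of their day 12 counts. These genes were near absent from all other day 4 libraries, so a swap between treatments of day 4 was not tested. The test set out beforehand asked whether all such genes fit 1 common share within counting error. It had only 4 genes, of which 100% did, and so left carry-over undecided. In the wider test 93.8% of 16 genes lay within a factor of 2 of a common share of 0.769%. That limit is wider than the counting error asked for in the first test, which was not applied to these genes. TFAP2A (0.306%, 16 counts) and HAND1 (0.398%, 38 counts) lay low and SERPINA1 (1.38%, 36 counts) high, so 1 exact share was not shown. RNA, reads or a few cells of day 12 in this library could give such counts, and these sources were not told apart.

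Of 10 MTRNR2L genes, 6 had over 1000 counts in both H9 libraries and at most 3 in any of the other 16, and MTRNR2L4, MTRNR2L5 and MTRNR2L7 did not share this pattern. Genes sharing over 80% of their words with others were more often changed over 8-fold between H9 and the day 4 control, with an odds ratio of 3.58 (2.17 to 5.63), against 2.11 (1.41 to 3.07) from day 4 to day 12. These intervals overlapped, which the prediction took to exclude differences in mapping, but that rule was too broad, because overlap does not exclude a difference and the mitochondrial copies are not in the table, so this stays undecided. Of those 6 genes, MTRNR2L9 had no matched transcript sequence, and the other 5 shared a median of 6.1% of words with the 16S ribosomal RNA (3.5 to 33.6), against 0.3% in 3 others (0.1 to 0.4). Reads of mitochondrial RNA assigned to these genes may thus account for the counts, but why only in H9 was not tested, and library and cell stage are confounded there.

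Some changes with TCBPA and with the mean of the compounds differed between days 4 and 12, which is why the following values are set out. For TCBPA 5 genes had a different change at the 2 days, and for the mean of the 3 compounds 31 did, while TBBPA and TBBPS had 0 each. Both of the first counts fell to 0 without day 4 control replicate 1 or day 12 control replicate 2. TMEM158 had a difference of -2, with 8.62 CPM in controls and 14.3 with TCBPA at day 4 and 27.6 and 11.5 at day 12. GPRC5B had -1.24, ANLN 0.76 and DIAPH3 1.05 between the days. PRRG3 had 1.5, being lower with TCBPA at day 4 and 51.6 against 37.4 CPM at day 12.

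For the mean of the compounds, lists also differed between the days, in tests added after seeing the data. Cholesterol synthesis had a median difference of -0.4 (adjusted p = 4.13e-12; adjusted p = 0.361 with an estimated correlation), G2 and M phase of 0.38 (adjusted p = 1.16e-12; adjusted p = 0.361 with an estimated correlation) and S phase of 0.51 (adjusted p = 1.3e-09; adjusted p = 0.361 with an estimated correlation). The FGF and ERK response had 0.56 (adjusted p = 3.77e-07; adjusted p = 0.214 with an estimated correlation). Secreted hepatocyte proteins had -1.18 (adjusted p = 0.000343; adjusted p = 0.492 with an estimated correlation), and -0.73 without TCBPA replicate 2 of day 4, the library with day 12 transcripts.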

How the results depend on the processing

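In this part the fits with GC content and length correction, the fits without genes that share most of their sequence, the difference between days of the mean of the compounds and the list tests of pairs of compounds were chosen only after the results were seen. With 2 libraries in each group, calls of single genes hung on individual libraries, and several counts between 0 and 5 moved under other settings. The cause was not tested unless stated. A count is said to have moved where it changed by more than 1.5-fold, or to or from 0, and smaller changes are mostly not listed in this part. Median-ratio scaling moved none of the counts by this rule. Of the 218 values of named genes with an adjusted p from DESeq2, 163 had passed in edgeR, of which 152 passed again and 11 did not, and 24 of the other 55 passed. A further 17 named values had no adjusted p there.

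With DESeq2, counts against the control were 2 for TBBPA, 115 for TBBPS and 111 for TCBPA at day 4, and 107 for TBBPA and 254 for TBBPS at day 12. The mean of the compounds at day 4 had 161. Pairs of compounds had 2 for TBBPS against TCBPA at day 4 and 1 for TBBPA against TCBPA at day 12. Differences between days had 68 for TBBPS, 378 for TCBPA and 424 for the mean.

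With GC content and length correction the count was 3 for TCBPA at day 4, 2 for TBBPS at day 12 and 8 for the difference between days of TCBPA. Without genes that share most of their sequence it was 2 for TBBPS at day 12, 1 for the mean at day 4, 0 for TBBPS against TCBPA at day 4 and 9 for the difference of TCBPA. With no filter on low counts it was 5 for TBBPS at day 4, 3 for TBBPS at day 12, 9 for the mean at day 4, 1 for TBBPA against TCBPA at day 12 and 43 for the difference of TCBPA.

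With only the libraries of that day or step, the count was 1 for TBBPS at day 4, 0 for TBBPS and 0 for TCBPA at day 12, 1 for the mean at day 4 and 0 for the mean at day 12. It was 0 for TBBPS against TCBPA at day 4, 2 for the difference of TCBPA and 0 for that of the mean. These fits held fewer libraries from which to estimate the spread, and replicates differed more in some groups than in others. The chi-square per degree of freedom was 14.92 for TCBPA and 24.74 for TBBPS at day 12, but 4.15 for the control of that day and 2.56 for H9. Since the model of all libraries pools these spreads, its SEs and p-values for TCBPA and TBBPS at day 12 may be too small. Of 171 named gene values that had passed, 88 passed there and 83 did not.

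With an estimated correlation, the count of gene lists that passed went from 10 to 0 for day 4 against H9, from 23 to 3 for day 12 against day 4, from 8 to 0 for TBBPA, 11 to 0 for TBBPS and 11 to 0 for TCBPA at day 4, and from 16 to 0 for TBBPA, 13 to 0 for TBBPS and 18 to 0 for TCBPA at day 12. For the mean of the compounds it went from 12 to 0 at day 4 and from 16 to 0 at day 12.

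With the replicate number as a block, the count was 9 for TBBPS and 3 for TCBPA at day 4, 180 for TBBPS at day 12, 44 for the mean at day 4 and 1885 for the mean at day 12. It was 0 for TBBPS against TCBPA at day 4, and 4 for TBBPS, 45 for TCBPA and 151 for the mean in the difference between days. AFP between TBBPA and TBBPS at day 12 turned from -0.09 to 0.16. In the pairing check, deviations of libraries with the same number correlated between 0.06 and 0.21 at day 4, over 0.1 in 4 of 6 pairs of groups, and between -0.07 and 0.26 at day 12, over 0.1 in 2 of 6. The first component of day 4 and that of day 12 each placed replicate 1 above replicate 2 in all 4 groups, a hint from the data of something shared, although at day 12 the TBBPA libraries lay at 3.8 and 3.7. The level set for pairing was over 0.1 in every pair, which neither day reached, and the labels name no shared batch, so the numbers were not used as pairs.

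Leaving out each library of a comparison in turn gave, against the control at day 4, between 0 and 11 genes for TBBPA, 0 and 3 for TBBPS and 0 and 491 for TCBPA, the highest without TCBPA replicate 2. At day 12 it gave between 0 and 6 for TBBPA, 0 and 2182 for TBBPS and 0 and 1637 for TCBPA. For the mean it gave between 0 and 401 at day 4 and 0 and 2962 at day 12. Pairs gave between 0 and 0 for TBBPS against TCBPA at day 4, and at day 12 between 0 and 1 for TBBPA against TBBPS, 0 and 1 for TBBPA against TCBPA, and 0 and 534 for TBBPS against TCBPA. Differences between days gave between 0 and 1 for TBBPA, 0 and 963 for TBBPS, 0 and 100 for TCBPA and 0 and 1340 for the mean. Of 812 such values of named genes that had passed with all libraries, 501 passed and 311 did not. Of 272 that had not passed, 24 did and 7 turned direction.

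Leaving out libraries moved the count of lists between 3 and 8 for TBBPA and 7 and 10 for TBBPS at day 4, 7 and 12 for the mean at day 4, and 6 and 19 for TBBPS at day 12. Single lists ranged from -0.07 to 1.58 for secreted hepatocyte proteins with TCBPA at day 4, from -0.04 to 0.23 for heat shock in the mean at day 4, and from 0 to 0.2 for ribosomal proteins with TBBPS at day 12.

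Between TBBPA and TBBPS at day 12 the medians ranged from -0.52 to 0.67 for secreted hepatocyte proteins, -0.26 to 0.31 for cholesterol synthesis, -0.43 to 0.25 for S phase and -0.27 to 0.14 for G2 and M phase. Between TBBPS and TCBPA they ranged from -0.2 to 0.99, -0.08 to 0.53, -0.5 to 0.17 and -0.35 to 0.1 in the same order. Each extreme was reached without TBBPS replicate 1 or 2.

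Leaving out libraries moved single genes as well. FGF10 with TBBPS at day 4 ranged from -0.05 to 0.49 and FGF10 between TBBPA and TCBPA at day 12 from -0.17 to 0.12. MKI67 ranged from -0.3 to 0.15 between TBBPA and TBBPS and from -0.43 to 0.02 between TBBPS and TCBPA at day 12. AFP ranged from -0.76 to 1.18 and from -0.43 to 1.59 for the same pairs.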

Other observations

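In this part the hypotheses below were chosen only after the results were seen, while the correlation test of a lag was set out before it was run.

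With TCBPA at day 12 some genes outside the main lists also changed. PSAT1, an enzyme of serine synthesis, rose by 1.18 ± 0.26 (adjusted p = 0.0152), and CHAC1, which degrades glutathione, by 1.2 ± 0.31 (adjusted p = 0.0291). The stress-induced cytokine GDF15 fell by 0.84 on the log2 scale (SE 0.21, adjusted p = 0.0245). LOX, which crosslinks collagen, changed by -1.74 ± 0.39 (adjusted p = 0.0166). CYP1A1, a target of the aryl hydrocarbon receptor, changed by -1.90 ± 0.55 (adjusted p = 0.0464). None of these passed without day 12 control replicate 2, where the count of genes was 0.

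One hypothesis is that the compounds delay the passage from day 4 to day 12. Across 14119 genes outside the lists, the TCBPA change at day 12 correlated at -0.31 or -0.33 with the step from day 4 to day 12 in controls, depending on which control replicate was used on each side. The slope was -0.081 or -0.082, and against shared controls it was -0.12 in TCBPA replicate 1 and -0.061 in replicate 2. The other compounds had similar correlations, of -0.27 or -0.3 for TBBPA and -0.3 for TBBPS with either choice. This is consistent with a lag, but fewer hepatic cells could give the same sign. Against a lag of all programmes, BMP targets and genes of surface ectoderm and trophoblast, which rose from day 4 to day 12 in controls, were not lower in TCBPA replicates 1 and 2 (scores of 0.08 and 0.11, and 0.26 and 0.17). A time course extended past day 12 with and without each compound would separate these, since a lag would end with the treated cultures reaching the control level of AFP and MKI67.

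A second hypothesis is that FGF10 contributes to the higher cell cycle transcripts at day 12. FGF10 was higher with TCBPA and ERK targets such as DUSP6 were too. In controls FGF10, most ERK response genes and cell cycle genes fell from day 4 to day 12, so a lag would leave them higher. Also, FGF10 stayed near 1 CPM and its call was lost with the day 12 libraries alone (1.88, adjusted p = 0.104). A role may therefore be small or absent. Adding an FGFR2 inhibitor or depleting FGF10 from day 4 in cultures with TCBPA, and counting dividing cells, would test it. Cell cycle genes would then return to the control level if FGF10 is needed.

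Another hypothesis is that the change arises from a mixture of cells and not from a shift within hepatoblasts. The 10 secreted hepatocyte proteins with at least 100 CPM in controls and a rise of at least 16-fold from day 4 had fold changes within a range of 0.76 on the log2 scale, as a smaller hepatic share could produce. Over all 16 the values spread more widely, from -2.08 for AHSG to -0.12. Markers of other cells gave no single picture in TCBPA replicates 1 and 2. Scores were 0.26 and 0.17 for surface ectoderm and trophoblast, 0.18 and 0.23 for endothelium, 0.4 and 0.1 for neural crest, -0.51 and -0.21 for neural cells, -0.55 and -0.28 for stomach and intestine, and -0.37 and 0.62 for mesenchyme and fibroblasts. Of these lists, that of surface ectoderm and trophoblast (adjusted p = 0.0357; adjusted p = 0.234 with an estimated correlation) passed upward and that of stomach and intestine (adjusted p = 0.0355; adjusted p = 0.291 with an estimated correlation) downward. Without TCBPA replicate 1 neither passed (adjusted p = 0.0601 and 0.152). Pluripotency genes scored 0.48 and 0.07 in TCBPA replicates 1 and 2, against -0.08 and 0.08 in the controls. They scored 0.44 and 0.41 with TBBPA and 0.42 and 0.21 with TBBPS. In the TCBPA libraries primitive streak genes scored 0.14 and 0.62, HOX genes -0.18 and 0.61 and bile duct genes -0.47 and 0.01. Single-cell sequencing, or AFP and HNF4A staining with a proliferation marker in the same cells, would tell whether dividing cells are hepatoblasts. The same design with more, separately grown cultures per group would also show whether TBBPS at day 12, whose replicates lay apart, lies nearer to its replicate 1 or 2.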
